A study of Homo sapiens with 8 samples.

How the data were processed

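RNA of dendritic cells from 8 HIV-1 controllers, 4 neutralizers and 4 non-neutralizers, was measured by bulk RNA sequencing. Per the labels' protocols, total RNA was extracted with a kit for low cell numbers and whole transcriptomes were amplified and tagmented by SMART-seq2; the gate that defined the cells is not given in the sources used here. The deposited values are estimated counts per gene, with 1 column per library, and the submitters made them with STAR and RSEM. Per the submitters' processing notes, the genome build was hg38; versions, settings and annotation are not given in the sources used here. SMART-seq2 does not mark strand and no molecular identifiers were counted, so overlapping and antisense genes and near-identical copies are uncertain, and intervals and floors cover counting error only.

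The table held 29937 genes, of which 29512 had an Ensembl ID in GENCODE 29, from which types and positions (1-based) were taken; 8361 had no symbol. Sex-informative genes were left out first, leaving 29817. Expected counts were rounded to whole numbers. Totals ran from 3.46 to 12.3 M (mega) counts. Of all counts, 10.7 to 24.4% lay in mitochondrial rRNA and 1.96 to 3.46% in 3 rows with equal values in all libraries, where only rows with over 10000 counts summed over the libraries were compared. Pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom 13.8 to 137), so none was counted as a duplicate.

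Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, minimum count 10 and minimum total 15, TMM normalization, quasi-likelihood F test, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM are TMM-normalized. Log2 CPM had a prior count of 2. Gene lists, 35 in all with 888 different genes of which 876 were in the table, were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and at least 5 tested members, adjusted over 33 lists. Separation was a pseudo-F of squared distances with an exact test over 35 splits. Library measures had an exact two-sided permutation test over 70 arrangements.

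Groups, main tests, the 35 lists, the rule for named genes and all alternatives but 5 were fixed before the data were examined. The share of mitochondrial rRNA was not among the library measures fixed then. Thinning, leaving out lymphocyte genes, a lymphocyte score as covariate, leaving out mitochondrial rRNA and, for lists, upper quartile scaling were added later, as were the further gene sets used to weigh explanations. The rule took, among called genes with a mean of at least 10 CPM and no overlap between groups, the 12 with the largest and the 12 with the smallest log2 fold change (11 qualified as lower), up to 4 called members of each list or else 2 with the smallest p, and 13 fixed dendritic cell and helper genes. The rule kept out most HLA genes, receptor segments and a set of genes whose level follows common inherited deletions. After values were seen, KLRC2, which the rule would have named, was also left out for such a deletion, as were the named members of the erythroid and neutrophil lists, which were not tested. Other genes that the rule named are not reported here.

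The model was checked on 5 simulated data sets of 11648 genes with the real means, library sizes and dispersions. Of genes changed by 2-fold, 2.54% were called, by 4-fold 45.9% and by 16-fold 91.3%, and 3.89% of 463 calls were unchanged genes. All 5 lists shifted by 2-fold and 0 of 100 unshifted lists were called; simulated genes were independent, which real ones are not. Alternatives covered normalization, filters, DESeq2 1.42.0, limma voom with and without quality weights, robust dispersion, thresholds, covariates, a surrogate variable from sva 3.50.0, the replicate number as a block, abundant genes left out, other list tests and each library left out in turn.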

Results

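RNA was sequenced from dendritic cells (given as mDC in the design), cells that take up antigen and present it to T cells, of people who control HIV-1. The cells of 4 neutralizer controllers were compared with those of 4 non-neutralizer controllers; each library came from a separate controller, and the series title ties the neutralizer label to breadth of neutralizing antibodies. The libraries were bulk SMART-seq2 libraries, an assay that amplifies full-length cDNA from few cells, so each value is an average over all cells in the tube. Total estimated counts, in M (mega) counts, were 12.3, 6.19, 5.83 and 6.13 in neutralizers 1 to 4 and 8.99, 3.46, 7.81 and 4.07 in non-neutralizers 1 to 4. A floor of 3 counts stood at 0.243 to 0.515 CPM (counts per M counts) in neutralizers and at 0.334 to 0.867 CPM in non-neutralizers. These floors were taken over total counts without TMM normalization, so they are only roughly on the scale of the gene values. Such floors cover counting error only. Of the 11648 genes with enough counts to be tested, 10438 were protein-coding.

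The comparison asked how the dendritic cell transcriptome of neutralizer controllers differs from that of non-neutralizer controllers. In neutralizers, genes typical of B cells, T cells and natural killer (NK) cells were higher, BLK by 74.5-fold, CD3E by 25.6-fold and PRF1 by 43.3-fold, together with chemokine genes and a few immediate early genes (EGR1 by 15.9-fold; n = 4 libraries per group). Without neutralizer 3 the log2 fold change of BLK was 5.61 in place of 6.22. Fewer genes were lower, among them CLEC9A, a receptor of CD141 dendritic cells (cDC1) that binds dead cells. In all, 263 genes were higher and 16 lower in neutralizers (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), 1099 and 602 at an unadjusted p under 0.05. Of the genes called higher, 229 differed by at least 4-fold, and of those called lower, 8 did. The values of one group lay entirely above those of the other for 10.6% of the tested genes, where chance gives 2.86%, and for 257 of the genes called higher and all 16 called lower. The counts depended on the method: limma voom called 20 genes higher and 0 lower, DESeq2 563 and 127, and limma voom with quality weights 571 and 258. Leaving out 1 library gave 103 to 399 higher and 2 to 53 lower (103 and 3 without neutralizer 2, 134 and 4 without neutralizer 4, 155 and 2 without non-neutralizer 2, 122 and 8 without non-neutralizer 3, 114 and 3 without non-neutralizer 4, 399 and 47 without neutralizer 1, 317 and 53 without neutralizer 3).

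B cell genes rose in most of their list. BLK, a B cell kinase (ENSG00000136573, chromosome 8, 11486894 to 11564604), stood at 51.3 ± 37.3 CPM in neutralizers and 0.633 ± 0.544 CPM in non-neutralizers (mean ± SD, n = 4 each), a log2 fold change of 6.22 ± 0.77 (SE; adjusted p = 0.00315, edgeR). BANK1, a B cell scaffold, rose by 2.94 ± 0.36 on the log2 scale. FCRLA, FCRL2 and FCRL5, relatives of Fc receptors, TNFRSF13B, a receptor for B cell survival factors, and EBF1, a B lineage transcription factor, were among the genes with the largest rises, at 6.73 ± 1.02, 6.55 ± 0.92, 6.48 ± 0.82, 6.58 ± 1.04 and 6.34 ± 1.20. Without neutralizer 3, BLK and FCRLA had 5.61 and 6.08; the sizes for FCRLA, FCRL2, FCRL5, TNFRSF13B and EBF1 rest on 5 to 19 counts in non-neutralizers and were larger without non-neutralizer 3, 1, 1, 4 and 4, in that order. Of the 17 tested members of the B cell list, 12 were higher, 15 when adjusted over the list alone, and none was lower. The list had a camera adjusted p of 1.71e-20 with a preset correlation of 0.01, and an adjusted p = 0.114 with an estimated correlation. The mean log2 CPM of the list was 5.52 ± 0.88 in neutralizers and 0.974 ± 0.418 in non-neutralizers. Of 35 tested immunoglobulin and T cell receptor genes, 30 were higher and 0 lower, and these genes held 0.492 ± 0.384% of the counts in neutralizers against 0.00610 ± 0.00252%.

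NK and cytotoxic genes rose in nearly the whole list. PRF1, which encodes the pore-forming protein perforin (ENSG00000180644, chromosome 10, 70597348 to 70602775), stood at 334 ± 129 CPM against 7.81 ± 5.23 CPM, a log2 fold change of 5.44 ± 0.60 (adjusted p = 0.00225, edgeR). CTSW, a protease of cytotoxic cells, and NKG7, a cytotoxic granule protein, rose by 3.86 ± 0.53 and 4.30 ± 0.64. TBX21, a transcription factor of NK and type 1 helper T cells, had 234 counts in neutralizers and 0 in non-neutralizers, at least 63.7-fold higher against a floor of 3 counts over the group. IFNG, the cytokine interferon gamma, had 2212 counts against 1, a ratio of 1807 with a 95% counting interval of 324 to 71400, and stood at 73.2 ± 53.0 CPM in neutralizers. Of 18 tested members, 16 were higher, 17 adjusted over the list alone. The camera adjusted p was 3.61e-21, and the adjusted p = 0.139 with an estimated correlation. The mean log2 CPM of the list was 5.77 ± 0.89 against 1.25 ± 0.95.

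T cell genes were higher as well. CD3E, a part of the T cell receptor complex (ENSG00000198851, chromosome 11, 118304545 to 118316175), stood at 55.2 ± 27.9 CPM against 2.22 ± 1.93 CPM, a log2 fold change of 4.68 ± 0.67 (adjusted p = 0.00469, edgeR). LCK, a T cell kinase, CD247, the zeta chain of the receptor complex, and CD6, a T cell surface receptor, rose by 4.86 ± 0.73, 4.93 ± 0.70 and 3.75 ± 0.47. TIGIT, an inhibitory receptor of T and NK cells, rose by 6.58 ± 1.11. Of 19 tested members of the T cell list, 8 were higher, 15 adjusted over the list alone; the camera adjusted p was 2.31e-15, and the adjusted p = 0.139 with an estimated correlation. The mean log2 CPM of the list was 4.80 ± 0.89 against 1.54 ± 0.89. Other genes with the largest rises were CCDC141 (6.48 ± 0.75), PPP2R2B (6.38 ± 1.22) and ZBTB32, a transcription repressor of lymphocytes, with 808 counts against 1, a ratio of 660 with a counting interval of 118 to 26100. Calls for PPP2R2B, EBF1 and TIGIT were lost in 4, 5 and 2 of the 8 fits without 1 library, each time without neutralizer 2 among them (log2 fold change without it 6.19, 6.16 and 6.16). Leaving out 1 library also moved CD247 to 4.25 (without neutralizer 4), LCK to 5.78 (without non-neutralizer 2), PPP2R2B to 5.68 (without neutralizer 1) and to 5.78, and TIGIT to 5.97 (both without non-neutralizer 1). Values for TIGIT and PPP2R2B without non-neutralizer 2, and for CCDC141 without non-neutralizer 3, were larger and rest on few counts.

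**Figure D1:**
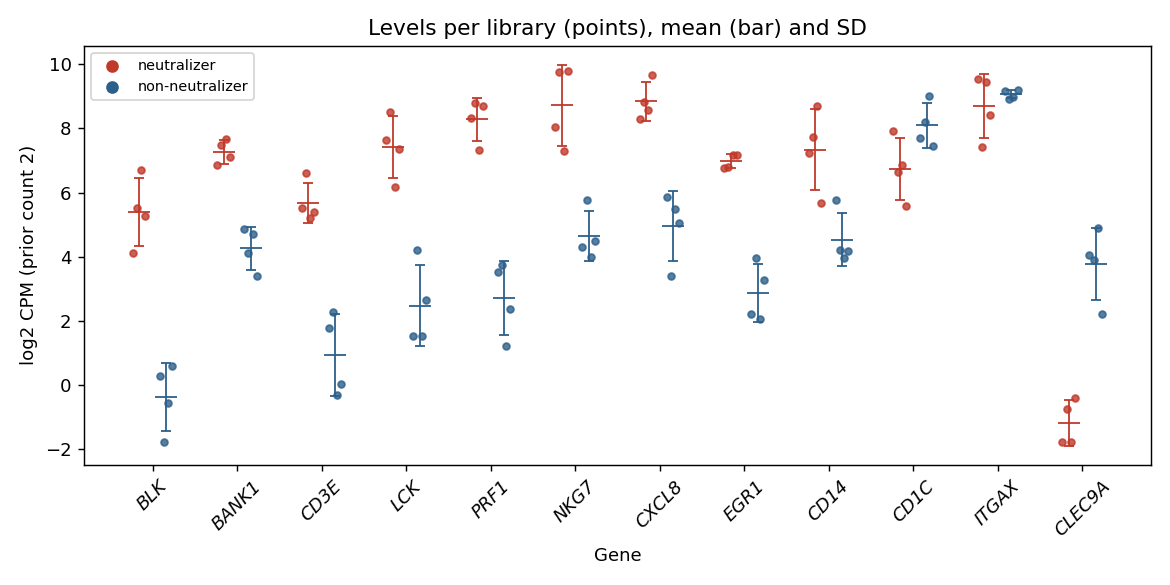
Level of 12 named genes in each library, in log2 CPM with a prior count of 2; points are libraries, the horizontal bar is the mean of 4 and the vertical bar the SD. B cell (BLK, BANK1), T cell (CD3E, LCK) and NK (PRF1, NKG7) genes lie apart between the groups, while ITGAX and CD1C overlap and CLEC9A is higher in non-neutralizers.

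Chemokine genes rose together with the B, T and NK lists, whose means differed by 4.54, 3.26 and 4.53 on the log2 scale. CXCL8, which attracts neutrophils (ENSG00000169429, chromosome 4, 73740506 to 73743716), stood at 491 ± 225 CPM against 36.5 ± 20.2 CPM, a log2 fold change of 3.74 ± 0.51 (adjusted p = 0.0046, edgeR). CXCL2 rose by 4.78 ± 0.63, and CCL5 and CCL4, which T and NK cells also make, by 5.50 ± 0.77 and 7.17 ± 1.03. CCL3 and CCL4 have near-identical gene copies that share reads, so their levels are uncertain. Much of the size of their rise came from neutralizer 4, with CCL4 at 755 CPM there against at most 256 CPM in the other neutralizers; without it CCL4 had a log2 fold change of 6.07, and CCL3 one of 3.67 and no call (adjusted p = 0.0726, edgeR). CCL5 had 6.55 without non-neutralizer 2. Of 10 tested chemokines, 8 were higher, also adjusted over the list alone. These include CCL3L3 and CCL4L2, copies of CCL3 and CCL4, so some calls may repeat the same reads. The list's camera adjusted p was 4.71e-08, and its adjusted p = 0.139 with an estimated correlation.

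NF-kB targets and immediate early genes were higher in part of their lists, in the group in which the B, T and NK lists were higher and the mitochondrial rRNA share was 19.5 ± 3.55% against 12.9 ± 1.49%. TNFAIP3, an NF-kB feedback inhibitor, stood at 678 ± 346 CPM against 84.5 ± 43.8 CPM (log2 fold change 3.00 ± 0.47), and IL1B, an inflammatory cytokine, at 201 ± 46.2 CPM against 45.8 ± 25.3 CPM (2.13 ± 0.48). EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 138465490 to 138469315), stood at 126 ± 19.1 CPM against 8.21 ± 5.28 CPM, with a log2 fold change of 3.99 ± 0.45 (adjusted p = 0.00243, edgeR). CCL3 rose by 4.85 ± 1.00, and EGR2, PPP1R15A and BTG2 rose by 6.09 ± 1.19, 1.32 ± 0.28 and 1.49 ± 0.32. Of 34 tested NF-kB genes 5 were higher, among them CXCL8, CCL4 and CCL3, which are also on the chemokine list. Adjusted over the NF-kB list alone, 9 were higher and 1 lower. Of 31 immediate early genes 4 were higher, 11 adjusted over the list alone. The camera adjusted p values were 5.62e-07 and 5.12e-07, and with an estimated correlation the adjusted p values were 0.261 and 0.163. EGR2 had 5.19 without neutralizer 4 (adjusted p = 0.0711, edgeR), and more without non-neutralizer 4. Calls for IL1B, PPP1R15A, EGR2 and BTG2 held in only 1, 2, 4 and 3 of the 8 fits without 1 library, whereas those for CXCL8, CXCL2, CCL5, TNFAIP3 and EGR1 held in all 8.

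Among cytokines that act on helper T and B cells, IL12A, a subunit of interleukin 12, had 203 counts against 2, a ratio of 82.9 with a counting interval of 22.7 to 689, and 2 of 13 members were higher, IL12A and IL1B. The list did not pass with camera (adjusted p = 0.0686) and passed with fry (adjusted p = 0.0197), which does not compare it with other genes. Its mean log2 CPM per library did not overlap between the groups, at 3.78 to 4.44 in neutralizers against 3.07 to 3.63 (exact two-sided permutation p = 0.0286, the smallest possible). Of 25 chemokine and migration receptors 3 were higher, 4 adjusted over the list alone: CXCR5, a homing receptor of B and follicular helper T cells (log2 fold change 4.35 ± 0.81), CXCR3 (3.28 ± 0.64) and S1PR1 (3.48 ± 0.78). Lymphocytes also express these receptors. Their calls held in 3, 2 and 1 of the 8 fits without 1 library, and those for IL12A, MKI67, RRM2, OPTN and CCL3 in 4, 6, 4, 4 and 4; leaving out neutralizer 2 ended the calls for CXCR5, CXCR3, S1PR1, IL12A and MKI67 (log2 fold change 4.09, 3.26, 3.13, 6.19 and 2.76). That list did not pass (camera adjusted p = 0.105). Of 25 cell cycle genes 2 were higher, MKI67 (3.08 ± 0.55), a marker of dividing cells, and RRM2 (4.46 ± 0.91, and 5.31 without non-neutralizer 3); the list had a camera adjusted p of 0.00144 and an adjusted p = 0.488 with an estimated correlation. Its call was lost without neutralizer 2 (mean difference 0.55 in place of 0.99, adjusted p = 0.0867, camera), which stood highest at a list mean of 4.55, while neutralizer 1, at 2.01, lay below non-neutralizers 1 and 3 (2.29 and 2.74; exact permutation p = 0.114 between the groups). The B, T and NK list means and the mitochondrial rRNA share were higher in the same group. OPTN, an autophagy receptor, was the 1 gene higher among 49 of lysosome and autophagy (4.47 ± 0.93, and 5.93 without non-neutralizer 2; list adjusted p = 0.232). The cholesterol and fatty acid synthesis list passed (camera adjusted p = 0.0213) with none of its 30 members called, LSS at 1.84 ± 0.63, and had an adjusted p = 0.435 with an estimated correlation. Its call was lost without neutralizer 4 or non-neutralizer 2 or 4 (mean difference 0.41, 0.47 and 0.50).

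Genes of cDC1 and CD1c dendritic cells were lower as lists and seldom as single genes, in the group in which the B, T and NK list means were higher by 4.54, 3.26 and 4.53 on the log2 scale. CLEC9A (ENSG00000197992, chromosome 12, 10030677 to 10066027) stood at 0.194 ± 0.233 CPM in neutralizers, 5 counts in all, against 16.2 ± 10.3 CPM in non-neutralizers, a log2 fold change of -6.35 ± 1.07 (adjusted p = 0.0117, edgeR). Without non-neutralizer 3 the CLEC9A log2 fold change was -5.86 (adjusted p = 0.0552, edgeR); without neutralizer 4 the fall was larger and rests on few counts. It was the 1 gene called among 16 of the cDC1 list, 2 adjusted over the list alone; the list's camera adjusted p was 5.62e-04, and its adjusted p = 0.435 with an estimated correlation. None of 16 genes of CD1c dendritic cells (cDC2) passed. CD1C, FCER1A and CLEC10A, which mark these cells, had log2 fold changes of -1.25 ± 0.48, -1.53 ± 0.60 and -1.02 ± 0.55, and CACNA2D3 one of -1.68 ± 0.63. This list's camera adjusted p was 0.00307, and its adjusted p = 0.488 with an estimated correlation. With the mean of the B, T and NK lists as a covariate, which is nearly collinear with the groups, both lists turned higher, cDC2 by 2.16 (camera adjusted p = 0.00166) and cDC1 by 2.70 (camera adjusted p = 0.00154). ITGAX, which encodes CD11c of myeloid cells, had a log2 fold change of -0.15 ± 0.39, whose sign turned in the fit without neutralizer 2. Non-classical monocyte genes were lower as a list with 0 of 18 called (camera adjusted p = 3.38e-05; adjusted p = 0.488 with an estimated correlation), with TCF7L2 at -2.24 ± 0.66 and MS4A7 at -1.97 ± 0.64. The means of these lists overlapped between the groups (exact two-sided permutation p = 0.0857, 0.114 and 0.114).

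Markers of other cells gave mixed results. Plasmacytoid dendritic cell genes did not pass as a list (camera adjusted p = 0.0842), while 3 of 13 were higher: JCHAIN, also made by plasma cells (6.07 ± 1.03), SPIB, also a B cell factor (1.90 ± 0.34), and GZMB, also made by NK cells (6.01 ± 1.25). The list of AXL SIGLEC6 dendritic cells, a rare type, passed (camera adjusted p = 0.036; adjusted p = 0.488 with an estimated correlation) with CD22, also a surface receptor of B cells, the 1 called gene of 8 (2.81 ± 0.35). Its call was lost without neutralizer 1, 2 or 3 or non-neutralizer 2 or 4 (mean difference 0.57, 0.90, 0.84, 0.69 and 0.71 in place of 0.92). CD14, the monocyte receptor for bacterial lipopolysaccharide, rose by 2.97 ± 0.62 and was the 1 called gene of 20 on the classical monocyte list, which did not pass (camera adjusted p = 0.955). The call for CD14 held in 3 of the 8 fits without 1 library and was lost without neutralizer 2 or 3 or non-neutralizer 2, 3 or 4 (CD14 log2 fold change 2.96, 2.37, 2.81, 2.76 and 2.81). Without non-neutralizer 1 it was 3.59. Calls for SPIB and GZMB held in 5 and 3. JCHAIN stood at 1147 and 525 CPM in neutralizers 2 and 3 against 84.2 and 96.2 CPM in 1 and 4, and had a log2 fold change of 5.09 without neutralizer 2; GZMB had 5.42 without neutralizer 4 (adjusted p = 0.0776, edgeR) and more without non-neutralizer 2. None of 8 platelet genes was called (list adjusted p = 0.0624), with SPARC and SDPR at 2.63 ± 0.81 and 1.30 ± 0.66. The platelet list passed without neutralizer 1 or 4 or non-neutralizer 1 or 2 (mean difference 1.48, 1.45, 1.31 and 1.36), and the classical monocyte list without neutralizer 4 (0.63, adjusted p = 0.0292, camera). The erythroid list and the neutrophil and basophil list had too few tested members for a test.

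Few antigen presentation and antiviral genes were called, by a test that called 2.54% of 2-fold changes in the simulations. In the type I interferon list ISG20, an exonuclease, was the 1 called gene of 43 (1.91 ± 0.28), and NLRC5, a regulator of MHC class I genes, the 1 of 21 of the class I list (1.83 ± 0.31; 3 adjusted over the list alone). None of 17 interferon-gamma-induced genes was called (TAP1 0.80 ± 0.24, IRF1 1.05 ± 0.31), none of 21 HIV restriction factors (IFITM1 1.04 ± 0.31, IFITM3 -1.18 ± 0.54), none of 20 MHC class II genes (CTSS -0.88 ± 0.42, HLA-DRA -0.68 ± 0.33) and none of 14 co-stimulatory ligands (CD80 4.84 ± 1.30, CD40 1.02 ± 0.31; 2 adjusted over the list alone). CD86 and ICOSLG had log2 fold changes of -0.38 ± 0.34 and 0.73 ± 0.65, and TGFB1 one of 0.81 ± 0.52. In the list of nucleic acid and microbial sensing none of 36 was called (CLEC7A -1.20 ± 0.28, TRAF6 0.91 ± 0.28; 1 lower adjusted over the list alone). The camera adjusted p values of these lists were 0.737, 0.557, 0.557, 0.352, 0.0619, 0.303 and 0.727 in the order type I interferon, class I, interferon gamma, restriction, class II, co-stimulation and sensing. Fry's test for change in either direction passed for class I, interferon gamma, co-stimulation and sensing (adjusted p = 6.59e-04, 0.0285, 1.09e-04 and 0.00763, fry). It did not pass for type I interferon, restriction and class II (adjusted p = 0.104, 0.411 and 0.282, fry). The median and the mean difference had opposite signs for type I interferon (-0.01 and 0.03), sensing (0.05 and -0.05), class I (-0.04 and 0.11) and classical monocyte genes (-0.12 and 0.03, where camera's direction was lower). The class II list passed as lower without neutralizer 1 or 3 or non-neutralizer 1 or 4 (mean difference -0.49, -0.53, -0.53 and -0.51), and the co-stimulation list as higher without neutralizer 1 (0.94, adjusted p = 0.0275, camera). CD274, TNFSF4 and IL6 had too few counts to be tested.

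Several metabolic and surface lists were lower in neutralizers, whose libraries also had higher B, T and NK list means (by 4.54, 3.26 and 4.53 on the log2 scale) and a mitochondrial rRNA share of 19.5 ± 3.55% against 12.9 ± 1.49%. Nuclear-encoded oxidative phosphorylation genes had a mean difference of -0.51 on the log2 scale (camera adjusted p = 4.09e-10; adjusted p = 0.435 with an estimated correlation), with NDUFB5 the 1 called gene of 70 (-1.16 ± 0.26). Cytosolic ribosomal protein genes had a mean of -0.32 with 0 of 76 called (adjusted p 3.71e-05; 0.678 as an adjusted p with an estimated correlation), with RPS24 at -0.85 ± 0.26 and RPL23 at -0.98 ± 0.30. Inhibitory ligands and receptors had 0 of 24 called (CD300A -1.20 ± 0.28, LGALS3 -1.12 ± 0.30; 3 lower adjusted over the list alone; adjusted p 1.95e-04 and, with an estimated correlation, an adjusted p = 0.435). C-type lectins had 1 of 21, CLEC9A (2 adjusted over the list alone; adjusted p 0.007 and, with an estimated correlation, an adjusted p = 0.437). The C-type lectin call was lost without neutralizer 4 (mean difference -0.47 in place of -0.80, adjusted p = 0.215, camera), and the ribosomal mean was -0.21 without non-neutralizer 3. With the number of detected genes as a covariate, the calls of the inhibitory and C-type lectin lists were lost (mean difference -0.41 and -0.45, adjusted p = 0.0947 and 0.313, camera). So were those of the cell cycle, cholesterol synthesis and cDC2 lists (mean difference 0.45, 0.28 and -0.67, adjusted p = 0.239, 0.205 and 0.141, camera). Without the covariate the means were -0.74, -0.80, 0.99, 0.55 and -0.96, in that order. The type I interferon and platelet lists passed as higher with the covariate (mean difference 0.42 and 1.47, adjusted p = 0.00734 and 0.018, camera). The lists of heat shock (DNAJB1 0.90 ± 0.33, HSPA5 0.79 ± 0.29), glycolysis (SLC2A3 1.64 ± 0.48, PFKP 1.23 ± 0.38), mitochondrially encoded mRNAs (MT-ATP8 -0.43 ± 0.27, MT-ND5 0.38 ± 0.28) and cholesterol efflux (LPL -4.93 ± 1.54, NPC1 1.35 ± 0.44) did not pass and held no called gene, with adjusted p values of 0.245, 0.265, 0.85 and 0.51.

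Among the genes called lower with a mean of at least 10 CPM, which leaves out CLEC9A and others with larger falls at lower levels, COTL1, an actin-binding protein (ENSG00000103187, chromosome 16, 84565594 to 84618077), stood at 401 ± 106 CPM against 2211 ± 1091 CPM (log2 fold change -2.46 ± 0.41; adjusted p = 0.0105, edgeR). FAM110A, TPPP3, ZSWIM7 and PELI2 had log2 fold changes of -2.46 ± 0.54, -2.22 ± 0.52, -1.67 ± 0.39 and -1.60 ± 0.36. DSE, ROGDI, NUDT19, GNAQ and CEP63 fell by 1.58 ± 0.34, 1.49 ± 0.34, 1.38 ± 0.29, 1.35 ± 0.29 and 1.22 ± 0.28 on the log2 scale. No gene called lower was called in all 8 fits without 1 library, against 88 of those called higher. COTL1 held in 7 of these fits, all but that without neutralizer 2 (COTL1 log2 fold change -2.40; adjusted p = 0.0521, edgeR), FAM110A and NUDT19 in 3 and PELI2 in 0. Of the 16 genes called lower, 1 was also called with detected genes as covariate and 0 with limma voom or with the replicate block. All 16 were also called with DESeq2. Within each group COTL1 went partly with the non-classical monocyte list mean. Both were lowest among non-neutralizers in non-neutralizer 3 (762 CPM and 5.77) and highest among neutralizers in neutralizer 3 (558 CPM and 7.46). Between these libraries the order was opposite, with the higher list mean beside less COTL1. Whether a different content of such cells accounts for the genes called lower was not tested.

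**Figure D2:**
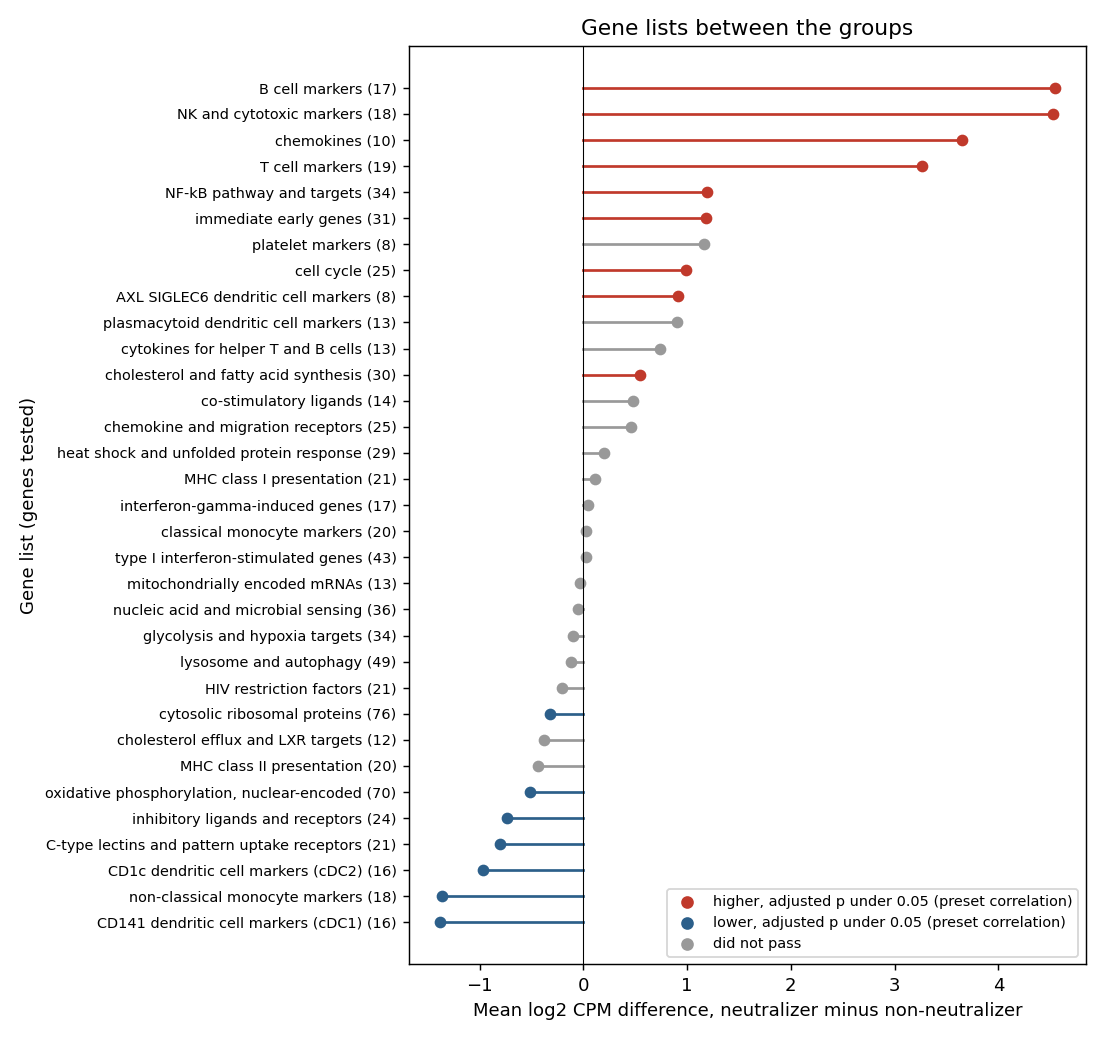
Mean log2 CPM difference of each tested gene list, neutralizer minus non-neutralizer, with the number of genes tested in parentheses; color shows whether camera with a preset correlation of 0.01 gave an adjusted p under 0.05. B cell (4.54), NK (4.53), chemokine (3.65) and T cell (3.26) lists differ most, and with an estimated correlation no list passed.

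Of 33 tested lists, 9 were higher and 7 lower with the preset correlation. With an estimated correlation 0 passed, 6 had an unadjusted p under 0.05, and 7 passed with fry. Whole profiles of the groups lay apart (pseudo-F 2.67, exact permutation p = 0.0286, the smallest the 35 splits can give). Neutralizer profiles were less alike: Spearman correlations across genes, which are not independent replicates, averaged 0.833 within neutralizers, 0.917 within non-neutralizers and 0.815 between groups. Neutralizer 1 stood apart on the second component.

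**Figure D3:**
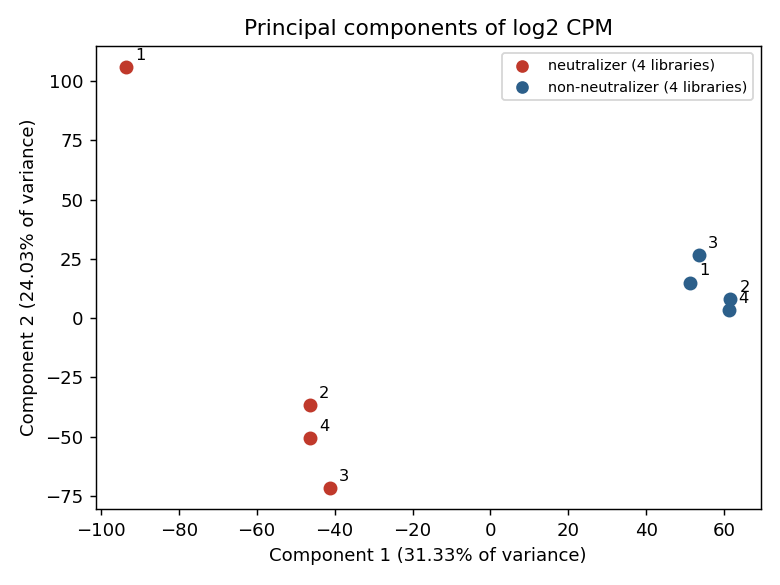
Libraries on the first 2 principal components of log2 CPM, which held 31.3% and 24.0% of the variance; numbers are replicate numbers, which name separate controllers. The groups part along component 1, and neutralizer 1 lies at 106 on component 2, away from the other libraries.

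Of 16 library measures, 5 had an exact two-sided permutation p of 0.0286, the smallest possible (adjusted p = 0.0914 for each of the 5). They were the means of the B, T, NK and plasmacytoid lists and the share of mitochondrial rRNA, a measure not fixed beforehand. That share was 19.5 ± 3.55% in neutralizers and 12.9 ± 1.49% in non-neutralizers. None passed after adjustment. More of the 16 measures would have to reach that smallest p for any to pass, so this failure decides nothing. On the plasmacytoid list only JCHAIN, SPIB and GZMB were called, genes also of plasma, B and NK cells. Its median difference was 0.34 against a mean of 0.91. Total counts, at 7.61 ± 3.13 and 6.08 ± 2.73 M, differed by less than the spread between libraries (exact permutation p = 0.514).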

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

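The tests of the 3 patterns weighed here were chosen only after the result was seen; the splits of the samples were chosen before.

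Genes of B, T and NK cells were higher in neutralizer libraries: 36 of 54 tested genes of the 3 lists were called. The tables argue against library size as the cause, since 91.7% of these calls remained after all libraries were thinned to the smallest total. RNA from lymphocytes among the collected cells is a candidate explanation: in a further list of 22 lymphocyte genes, from which genes known to be called had been left out, 17 of 19 tested had a positive log2 fold change, with a median of 1.48 and none called by edgeR. The most abundant genes of the 3 lists, NKG7 and MS4A1, stood at 542 ± 387 and 453 ± 192 CPM in neutralizers, and 9 of the 54 tested genes had at least 10 CPM in non-neutralizers too, CD79B at 104 ± 53.8 CPM; 3 of the 54 are on another list as well. The gate is not given in the sources used here, so whether it should have removed such cells is open; expression by the dendritic cells and a difference that goes with neutralization were not tested and stay open.

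CLEC9A was lower in neutralizers. Dilution by RNA of other cells would lower it about as much as other dendritic cell genes. The log2 fold change of CLEC9A minus the median of the cDC2 list was -5.46, against an SE of 1.07 that covers CLEC9A alone. On that list 13 of 16 genes had a negative log2 fold change, at the lowest -1.87 ± 1.22 (CD1B). These values argue against dilution as the whole cause, although CLEC9A was picked because it had been called. Fewer cDC1 cannot be told apart from lower CLEC9A in each cell. XCR1, CADM1 and CLNK, picked from the same cDC1 list after the result was seen, had a median log2 fold change of -1.19. Their fall was smaller than that of CLEC9A, but their SEs were 1.47, 1.08 and 1.25 and the libraries differed. Of the 16 tested genes of that list, 12 had a negative and 4 a positive log2 fold change. BATF3 stood at -1.87 ± 0.63, and THBD, which encodes CD141, at 0.43 ± 0.60. Neutralizer 1 had XCR1 at 23.7 and CLNK at 9.24 CPM with 0 counts of CLEC9A and of CADM1, so its values go both ways. Neutralizers 2 to 4 had at most 1.09 CPM of XCR1 and 0.735 CPM of CLNK with CADM1 at 4.59 to 14.8 CPM. Non-neutralizer 4 had XCR1 and CLNK at 1.21 CPM each with CLEC9A at 4.36 CPM. A biological difference between the groups stays open, untested.

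Of 10 tested chemokines 8 were higher, of 34 NF-kB genes 5 and of 31 immediate early genes 4. These calls are not all separate: CXCL8, CCL4 and CCL3 are on both the chemokine and the NF-kB lists. The chemokine calls also include CCL3L3 and CCL4L2, near-identical copies of CCL3 and CCL4. None of these lists passed with an estimated correlation (adjusted p = 0.139, 0.261 and 0.163, camera). That lymphocytes alone carried them cannot be told apart from a change in myeloid cells: 9 tested inducible myeloid genes outside the lists had a median of 0.14 with quartiles of -0.48 and 1.04. CD14 monocytes among the cells stay open, since the test compared 7 other classical monocyte genes with CD14 and not with these lists. The 7 genes, with low levels in non-neutralizers, had a median of 0.53 and an upper quartile of 1.13, against 2.97 ± 0.62 for CD14. Of these, 6 had a positive log2 fold change, CLEC4E one of 2.50 ± 1.12. F13A1, CD163 and CES1 already stood at 46.2 ± 31.4, 34.8 ± 17.0 and 29.5 ± 27.5 CPM in non-neutralizers, where added monocytes would change them less. Handling before lysis was not tested, and neither was a biological difference; the mitochondrial rRNA share, 19.5 ± 3.55% against 12.9 ± 1.49%, differed between the same groups (exact permutation p = 0.0286).

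All 35 splits of the 8 libraries into 4 and 4 were compared. The real one was the 1 split with at least 263 genes in one direction (highest other 24). Its share of 0.0286 is the smallest that 35 splits can give. The count of genes called higher thus passed the 0.05 level set beforehand. That share was not adjusted over the other split tests, so it does not by itself exclude chance. For the 16 genes called lower, 2 splits gave as many (highest other 24), so that level was not passed and chance cannot be excluded. For lists it cannot either: 11 splits gave at least 9 lists in one direction and 20 gave at least 7, with 13 as the highest of the others.

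In 224 groups of 4 values, 13 had a library far from the other 3 by Dixon's criterion at the 95% level, where chance gives about 11.2. In neutralizer 1, total counts were 12.3 M (mega counts) against 5.83 to 6.19 M, and log2 CPM was 3.12 for FCRL2 (others 4.85 to 5.17), 1.37 for EBF1 (4.85 to 5.17) and 5.82 for ISG20 (6.36 to 6.46). The T cell list mean was 6.13 in neutralizer 2 (4.19 to 4.51). In log2 CPM, ZBTB32 was 5.34 in neutralizer 3 (4.58 to 4.61), MS4A7 8.70 in neutralizer 3 (6.12 to 6.56) and CD22 5.44 in neutralizer 4 (6.11 to 6.14). CD14 was 5.76 in non-neutralizer 1 (3.97 to 4.22) and IL1B 3.27 in non-neutralizer 2 (5.61 to 6.03). IFNG at -0.70 in non-neutralizer 2, ZBTB32 at -0.90 in non-neutralizer 4 and IL12A at -0.87 in non-neutralizer 3 rest on 1 or 2 counts, with the others of the group at 0 counts (-1.78).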

How the results depend on the processing

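Chosen after the data were seen were thinning, leaving out lymphocyte genes, the lymphocyte score, leaving out mitochondrial rRNA and, for lists, upper quartile scaling. The cause was not tested for the changes below, except that fewer genes or libraries enter some fits. Main counts were 263 genes higher and 16 lower. The count higher or lower moved to 725 and 212 with no low-count filter, 563 and 127 with DESeq2, 20 and 0 with limma voom, 571 and 258 with quality weights, 398 and 66 at FDR below 0.1, 134 and 9 with detected genes as covariate, 161 and 7 without lymphocyte genes, and 0 and 0 with the lymphocyte score as covariate, which is nearly confounded with the groups; upper quartile gave 30 lower. Voom's 20 were all among the 263. With detected genes as covariate, 131 of the 134 higher but only 1 of the 9 lower were among the main calls. The replicate numbers name separate donors and do not pair the libraries (correlations of deviations 0.031, 0.037, -0.163 and 0.047; 1 of 4 neutralizers correlated best with its own number): with the replicate block 134 genes were higher and 0 lower, and with replicate block and detected genes 29 and 1. Without each library in turn, 103 to 399 genes were higher and 2 to 53 lower, 7 to 10 lists higher and 6 to 8 lower, pseudo-F was 2.17 to 3.25, and 3 to 6 library measures had an exact p under 0.05. Of the 279 genes called, none changed sign in the alternatives that tested it, other than the lymphocyte score, with which 57 did. Lists moved from 9 higher and 7 lower to 0 and 0 with an estimated correlation, 0 lower with fry, 4 lower with detected genes, 5 higher without lymphocyte genes and 2 lower with the lymphocyte score. Pseudo-F was 7.58 with the 500 most variable genes, 2.91 with Spearman distances, 2.67 with DESeq2 size factors and 3.82 with a mean CPM of at least 10; its exact p stood at the smallest possible, 0.0286, in each of these, so it cannot show stability.

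Of 2507 values of 94 named genes under alternatives, 2039 kept their side of the threshold and sign, 365 were weaker, 75 stronger and 28 reversed; of 624 list values, 520 were the same, 49 weaker, 18 stronger and 37 reversed. Reversed log2 fold changes with the lymphocyte score as covariate were IRF1 -0.18, IFITM1 -0.16, IFITM3 0.13, HLA-DRA 1.82, CD40 -0.0029, CCL5 -0.16, CXCR5 -0.39, S1PR1 -4.03, BTG2 -0.10, DNAJB1 -2.10, HSPA5 -0.56, NPC1 -1.86, OPTN -1.24, CACNA2D3 2.32, CD1C 1.60, JCHAIN -2.08, GZMB -3.77, NKG7 -0.81, FCER1A 2.44, CLEC10A 1.85, ITGAX 3.04 and CD86 0.64. ITGAX reversed to 0.18 with detected genes, 0.13 with the block and detected genes and 0.14 without neutralizer replicate 2 (range without 1 library -0.43 to 0.14), and ICOSLG to -0.22, -0.37 and, without neutralizer replicate 4, -0.25 (range -0.25 to 1.03). List means reversed with the lymphocyte score were HIV restriction 0.037, sensing 0.42, class II 0.62, class I -0.32, heat shock -0.81, cell cycle -1.69, cDC2 2.16, cDC1 2.70, plasmacytoid -0.38, T cell -1.79, NK -0.16 and platelet -4.08. With detected genes HIV restriction was 0.018, sensing 0.12 and mitochondrial mRNAs 0.12. With mean CPM of at least 10 mitochondrial mRNAs were 0.00040 and classical monocytes -0.019; with upper quartile type I interferon was -0.037, interferon gamma -0.016 and classical monocytes -0.036; thinned, co-stimulation was -0.011 and classical monocytes -0.034. Without 1 library, type I interferon was -0.15, -0.14, -0.12, -0.074 and -0.031 (highest 0.30), sensing 0.063, 0.083 and 0.0037 (list mean: nucleic acid and microbial sensing, lowest -0.0857), mitochondrial mRNAs 0.084 and 0.096 (lowest -0.13), and classical monocytes -0.029, -0.15, -0.34, -0.10 and -0.11 (highest 0.63). Depth limits genes near 3 counts, such as IFNG in non-neutralizers.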

Other observations

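Further lymphocyte genes outside the fixed lists were written down after the fixed lists were tested, with genes known to be called left out. Of 19 tested, 7 were higher in every neutralizer than in any non-neutralizer. None passed the test across all genes, which that choice of genes made likely beforehand. RASGRP1, an activator of Ras in T cells, stood at 27.4 ± 16.8 CPM against 1.61 ± 1.48 CPM (log2 fold change 4.23 ± 0.99, adjusted p = 0.0519, edgeR), and PRKCQ, a T cell kinase, at 32.5 ± 19.6 CPM against 1.35 ± 1.56 CPM (4.59 ± 1.09, adjusted p = 0.0543, edgeR). Among these, SATB1 had a log2 fold change of -0.19 ± 0.31 and ADAM28, a B cell gene also at 76.0 ± 45.3 CPM in non-neutralizers, one of -0.06 ± 0.54. Of 9 tested inducible myeloid genes, TREM1, a receptor that amplifies inflammation, was higher in every neutralizer than in any non-neutralizer (log2 fold change 1.04 ± 0.36, adjusted p = 0.205, edgeR). IL1R2, a decoy receptor for interleukin 1, was lower in every neutralizer than in any non-neutralizer (log2 fold change -2.35 ± 0.72, adjusted p = 0.136, edgeR).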
